A study of Homo sapiens with 10 samples.

How the data were processed

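The data are 10 Affymetrix HG-U133 Plus 2.0 arrays of RNA from human dendritic cells (DCs), the cells that take up antigen and present it to T cells. The labels place 2 arrays in each of 5 groups: cells left unloaded, loaded with mRNA, loaded with a cell lysate, loaded with both from the same source (matched), and loaded with both from different sources (mismatched). The design text describes 44 populations (9 unloaded, 10 mRNA, 11 lysate, 7 matched and 7 mismatched), each from a different normal donor and matured for 48 h after loading. Whether an array carries RNA of 1 population or a pool of several is not given in the sources used here. Where nothing says that the 2 arrays of a group hold separate donors, p-values measure only the spread between these arrays.

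The deposited values are intensity on a linear scale, 1 signal per probe set, from biotin-labelled RNA on 1-colour arrays, per the labels' protocols. GCOS, the scanner maker's software, is the tool named in the submitters' processing notes, with no version. The rule by which the arrays were scaled is not given in the sources used here. All values lay above 0, the trimmed mean signal of the arrays ran from 90.3 to 109, and their median from 19.5 to 25.6, so the arrays were near a common scale without being equal. The values come with no detection calls in the table used here, so a dim signal has no stated background, and a dim gene is measured poorly. The number of arrays limits the precision.

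The file holds 54675 probe sets. Gene symbols came from the platform annotation, with current symbols looked up through gene identifiers; 0 symbols needed updating. A single symbol was found for 41097 probe sets, several for 1801, and 11777 are unnamed here; none was named from a probe set with several symbols. The 62 control probe sets were left out, as were XIST, TSIX and Y-linked genes, since arrays can come from single donors. Probe sets with a mean log2 above the median of all probe sets were tested, 27241 in number; the raw signal at that point was 19.7. For each of 11998 genes, the probe set with the highest mean stood for the gene, and other probe sets of the gene could disagree.

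Values were analysed as log2(signal + 32), so a fold change understates the change of a dim gene. A linear model with 5 group means was fitted over all 10 arrays with limma (version 3.58.1, R 4.3.3), with moderated variances that follow a trend with signal; 5 residual and 12 prior degrees of freedom stood behind each standard error. Adjusted p-values are Benjamini-Hochberg values over the 27241 probe sets of a comparison, with a threshold of 0.05. The 7 comparisons are matched cells against each of the other 4 groups, and mRNA, lysate and mismatched cells against unloaded cells. A further test asked for genes that passed in the same direction in all 4 matched comparisons, another for any difference among the groups, and an interaction test asked whether mRNA acted differently with matched lysate than without lysate.

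Gene lists (25 pathway lists and 11 lists of cell type markers) were fixed before the data were examined and tested with limma's camera against all other genes, on 1 probe set per gene, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with a correlation estimated from the residuals passed no list in any of the 7 comparisons. With it 10 of the 252 list tests had an unadjusted p under 0.05, no more than the share of 0.05 that unchanged lists would give. The list calls therefore rest on the preset correlation, and the adjusted p with an estimated correlation stands beside each list reported. The members of a list that passed on their own rest on the test of each gene. The count of list members past the threshold is given over all genes tested and adjusted over the list alone.

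Genes to be named were chosen by a rule fixed together with the lists. For each comparison it takes the 10 largest rises and the 10 largest falls that passed with no overlap between the arrays, up to 4 members of each list that passed, and up to 6 members of any list that passed on their own. It also takes 10 costimulation and cytokine genes whatever their p, and up to 12 genes each way for matched cells against all 4 groups. Not every gene picked is named in the text, and LAMP2 was passed over after its values were seen, since another of its probe sets fell while the one picked rose in 3 matched comparisons. The exceptions fixed with the rule are genes whose level can follow a donor's genotype, which hold some HLA genes but not others such as HLA-F and HLA-DMB; 1 further gene of this kind that they had missed was left out after its values were seen.

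The procedure was tested on simulated data with the real means and the moderated variances of the fit, which follow the trend with signal. The simulation thus cannot check that variance model. In the simulated matched against mismatched comparison of 27241 probe sets, 81% of 100 changes of 2-fold were called, 28% of 100 changes of 1.4-fold, and 9 of 27041 unchanged probe sets; the slope of fitted on true log2 was 0.993. For matched cells against all 4 groups the shares called were 71% and 22%, with 1 unchanged probe set. A simulated list of 20 genes moved by 0.3 had adjusted p = 2.15e-10, or 0.0238 with an estimated correlation, and 0 of 35 unchanged lists passed. The simulated noise was independent between genes. In the data the lists that passed in matched against mismatched cells had estimated correlations of 0.12 to 0.58. The simulation therefore cannot show how often the preset correlation would call an unchanged list of correlated genes. The alternatives tried were other pseudocounts, quantile normalization, median centring, other filters on dim probe sets, other variance models, the threshold of the design text, only the groups compared, 1 probe set per gene, a replicate block, each array left out in turn, and other list tests. The ratio of 3' to 5' signal of ACTB as a covariate, and a fit without the unloaded arrays, were added after the arrays had been seen. Figures were drawn with matplotlib (version 3.10.9).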

Results

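Gene expression was measured in human DCs that had been given antigen as mRNA, as lysate or as both, to ask whether a cell that receives mRNA and protein from the same source differs from one that receives them from different sources. The 10 arrays fall into 5 groups of 2: unloaded, mRNA, lysate, mismatched and matched. All values below are means of 2 arrays per group, differences are on the log2(signal + 32) scale, and errors are standard errors from the limma fit over all 10 arrays. Of 27241 probe sets tested, 3741 differed among the 5 groups, in 1898 of 11998 genes. The 2 arrays of a group correlated at 0.984 to 0.986 across probe sets, which are not independent replicates, and arrays of different groups at 0.972 to 0.983.

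The direction of many small differences depended on how the arrays were scaled. The median difference over all probe sets was -0.11 for matched against unloaded cells and -0.11 for lysate against unloaded cells, and it was near 0 after quantile normalization (0.008 and 0.002). Centring each array on its median moved the median difference of matched against unloaded cells by 0.15, of lysate against unloaded cells by 0.13, of matched against mRNA cells by 0.12 and of matched against mismatched cells by 0.10. The split of calls into higher and lower is therefore given under all 3 scalings. No gene named below as having risen or fallen changed its sign under either of the other scalings.

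**Figure D1:**
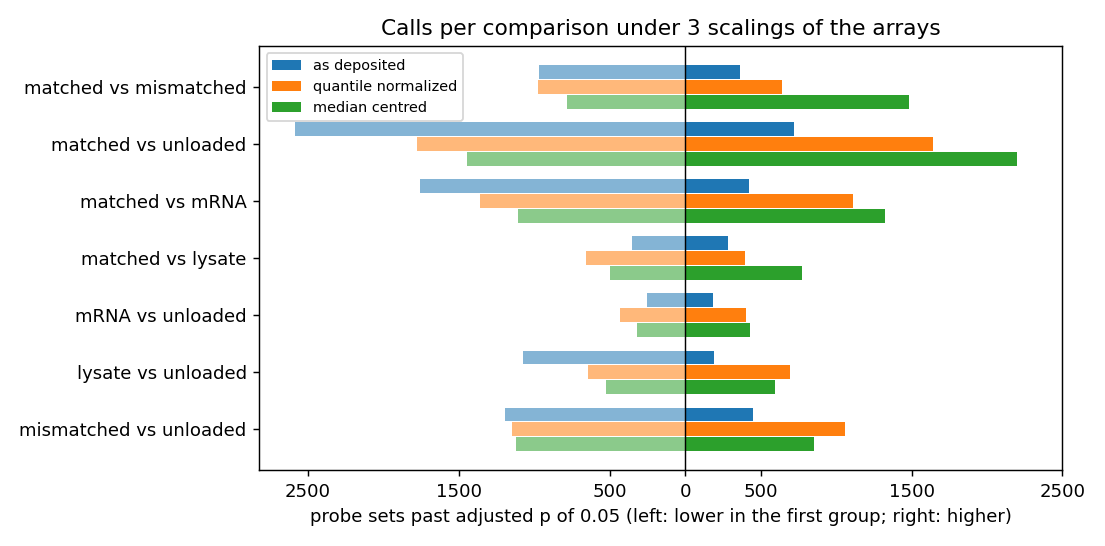
Number of probe sets past an adjusted p of 0.05 in each of the 7 comparisons, with bars to the left for probe sets lower in the first group and lighter in colour, and bars to the right for those higher. Colours show the values as deposited, after quantile normalization and after median centring; for matched against unloaded cells, 78.2% of the calls were lower as deposited, 52.1% after quantile normalization and 39.7% after centring.

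Matched cells were compared with mismatched cells, which had also received mRNA and lysate, but from different sources. By the design text the donors of these groups differ as well, so an effect of the shared source is not isolated. The extracellular chaperone CLU rose from a mean signal of 298 to 784 (log2 1.31 ± 0.10, adjusted p = 1.47e-06). The glycoprotein CD52 rose from 1840 to 3549 (0.94 ± 0.08), the cancer-testis antigen PRAME from 185 to 390 (0.96 ± 0.12), and the metalloproteinase MMP10 from 56.5 to 155 (1.08 ± 0.14). PSAT1, an enzyme of serine synthesis, had the largest fall, from 282 to 68.2 (-1.65 ± 0.11, adjusted p = 5.62e-07). The insulin receptor substrate IRS2 fell from 549 to 251 (-1.04 ± 0.11), and the transcription factors ETV6 and ZNF652 fell from 1260 to 611 and from 392 to 157. Asparagine synthetase, ASNS, fell from 139 to 55.4 (-0.97 ± 0.11). CHRNA3, RBMS3, DGCR5, CD300LB, KCNK1 and CBR3-AS1 also rose, and GTF2IP20, UTS2R, CACNG4, CAPN10 and CUEDC1 fell, but most of these were dim in 1 group.

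Cytokine and chemokine lists did not pass in matched against mismatched cells. Of 19 chemokines 1 rose and 3 fell (6 adjusted over the list alone, list adjusted p = 0.375), and of 15 T-cell polarizing cytokines 1 rose and 1 fell (4 adjusted over the list alone, list adjusted p = 0.987). EBI3, a subunit shared by the cytokines IL-27 and IL-35, rose from 976 to 1442 (0.55 ± 0.09, adjusted p = 0.00235), and the chemokine CCL17 from 11520 to 13920 (0.27 ± 0.06). IL12B, the shared subunit of IL-12 and IL-23, fell from 1541 to 1134 (-0.43 ± 0.09, adjusted p = 0.013). The neutrophil-attracting chemokines CXCL8 (2080 to 1337), CXCL5 (219 to 94.6) and CXCL2 (277 to 139) fell, as did the transcription factor IRF1 (1245 to 806) and the costimulatory receptor TNFRSF9 (934 to 574). The costimulatory gene CD86 had signals of 6157 and 7250 (0.24 ± 0.07, adjusted p = 0.055), and CD80, CD83 and CD40 had differences of 0.16 ± 0.08, 0.11 ± 0.06 and 0.15 ± 0.09 that did not pass. CCR7 differed by -0.06 ± 0.07 and IL6 by 0.01 ± 0.18, neither past the threshold, and IL12A, IL10 and TNF were not among the genes tested. After median centring CD80 (adjusted p = 0.0377), CD83 (0.206, adjusted p = 0.0294) and CD86 (0.333, adjusted p = 0.00203) passed. After quantile normalization these 3 differed by 0.095, 0.005 and 0.108 (adjusted p = 0.382, 0.957 and 0.101), and CCR7 passed on the lower side (-0.151, adjusted p = 0.0276), while its difference after centring was 0.042. CD86 also passed with a stricter filter (adjusted p = 0.0276), with robust variances (adjusted p = 0.0434) and with only the groups compared (adjusted p = 0.00837), but not with no filter (adjusted p = 0.199), with a variance that does not follow signal (adjusted p = 0.343) or with the ACTB ratio as a covariate (adjusted p = 0.144).

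**Figure D2:**
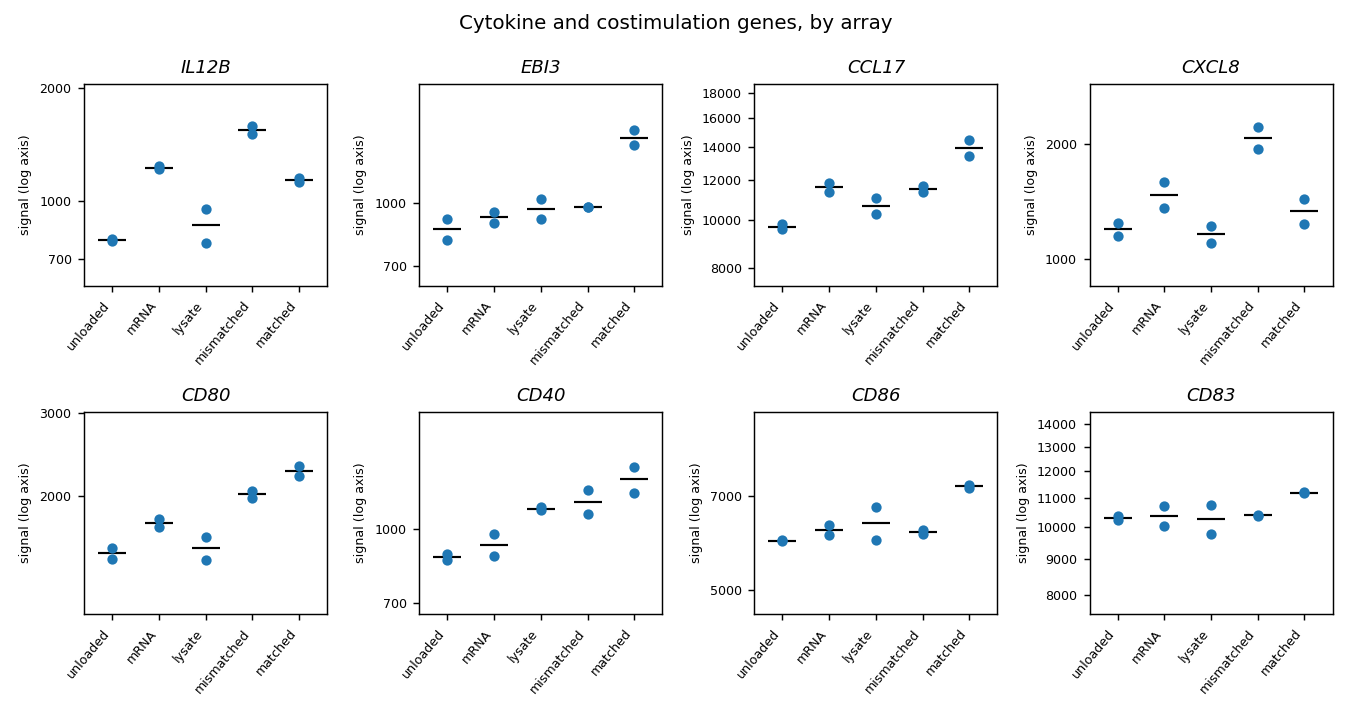
Signal of 8 cytokine and costimulation genes on each array, on log axes that do not start at 0. Each point is 1 array, horizontal lines are means of the 2 arrays of a group, and groups run from unloaded to matched cells; EBI3 reached 1442 in matched cells against 862 to 976 in the other 4 groups, and IL12B was highest in mismatched cells at 1541.

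In matched against mismatched cells, 7 of 36 lists passed, all of them higher in matched cells as deposited. Of 7 lists that passed after quantile normalization 5 were higher and 2 lower, and the medians of the MHC class I and ribosomal protein lists were then 0.007 and 0.03. After centring the medians were 0.168 for MHC class I, 0.226 for ribosomal proteins, 0.27 for interferon-stimulated genes, 0.282 for the proteasome, 0.271 for heat shock and 0.293 for oxidative phosphorylation. Of 24 proteasome subunits 1 rose and none fell (median 0.18, list adjusted p = 1.64e-06), with 8 past the threshold adjusted over the list alone; PSMB2 went from 1133 to 1432. Of 23 lysosome genes 4 rose (median 0.23, 10 adjusted over the list alone, list adjusted p = 1.82e-06), among them the protease CTSL (886 to 1262) and HEXA (275 to 431). Of 23 oxidative phosphorylation genes 5 rose (median 0.20, 6 adjusted over the list alone, list adjusted p = 1.09e-07), including CYC1 (665 to 1057). Of 27 cytosolic ribosomal protein genes 4 rose, RPL22 and RPS12 among them (median 0.13, 11 adjusted over the list alone, list adjusted p = 2.97e-09). Of 16 heat shock and chaperone genes HSPH1, HSP90AA1 and HSPB1 rose (median 0.17, 4 adjusted over the list alone, list adjusted p = 0.000247). Of 33 type I interferon-stimulated genes ISG15, XAF1 and MX1 rose (median 0.17, 4 adjusted over the list alone, list adjusted p = 0.00205). These 6 lists had adjusted p = 0.771 with an estimated correlation. Of 20 genes of MHC class I presentation 3 rose, HLA-F, PSME1 and PSMB9 (median 0.07, 3 adjusted over the list alone, list adjusted p = 0.0206), with adjusted p = 0.994 with an estimated correlation.

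In all, 1336 probe sets passed in matched against mismatched cells, 364 higher and 972 lower, in 577 genes (239 higher, 338 lower), of which 3 rose and 10 fell by more than 2-fold. The lower share was 72.8% as deposited, 60.3% after quantile normalization and 34.6% after centring. Without mismatched replicate 1 or 2 the count was 292 or 431, without matched replicate 1 or 2 it was 573 or 432, and with a variance that does not follow signal it was 169, where EBI3 (adjusted p = 0.0765), IL12B (adjusted p = 0.138) and CCL17 (adjusted p = 0.266) no longer passed. With no filter the count was 569 and CCL17 (adjusted p = 0.136) no longer passed, and with the ratio of 3' to 5' ACTB signal (2.1 and 1.95 on the matched arrays, 1.92 and 1.76 on the mismatched arrays) as a covariate it was 745 and neither CCL17 (adjusted p = 0.0579) nor IL12B (adjusted p = 0.0647) did. Their differences were about as large with it, 0.293 ± 0.080 for CCL17 and -0.424 ± 0.118 for IL12B, with wider errors.

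Matched cells were compared with unloaded cells, from which they differ in loading with both antigens from one origin and in donors. The eosinophil and basophil granule protein gene CLC rose from 72.1 to 355 (1.90 ± 0.13, adjusted p = 1.33e-07), the GTPase regulator ARHGAP22 from 49.3 to 251 (1.80 ± 0.15), CRABP2, which binds retinoic acid, from 72.9 to 202, and CD52 from 1687 to 3549 (1.06 ± 0.08). PSAT1 fell from 2135 to 68.2 (-4.44 ± 0.11, a 21.7-fold difference, adjusted p = 9.5e-14), ASNS from 897 to 55.4 (-3.41 ± 0.11, 10.6-fold), PHGDH from 312 to 35.1 (-2.36 ± 0.16), ALDH1L2 from 301 to 44.3 and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, from 992 to 255. The stress-induced inhibitor of mTOR, DDIT4, fell from 762 to 179 (-1.91 ± 0.12), the monocyte receptor CD14 from 158 to 11.8 (-2.13 ± 0.19) and the chemokine CCL26 from 376 to 78.4.

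Of 23 maturation and costimulation genes 5 rose and 3 fell in matched against unloaded cells, and the list did not pass (median 0.04, 11 adjusted over the list alone, list adjusted p = 0.136). CD80 rose from 1517 to 2262 (0.57 ± 0.08, adjusted p = 0.000145), CD40 from 875 to 1268 (0.52 ± 0.09, adjusted p = 0.00116), CD86 from 5965 to 7250 (0.28 ± 0.07, adjusted p = 0.0109), IL12B from 787 to 1134 (0.51 ± 0.09) and EBI3 from 862 to 1442 (0.72 ± 0.09). CD83 (0.12 ± 0.06), CCR7 (0.04 ± 0.07) and IL6 (-0.15 ± 0.18) did not pass, but after median centring CD83 (0.271, adjusted p = 0.00358) and CCR7 (0.19, adjusted p = 0.0328) did. After quantile normalization these 2 differed by 0.067 and 0.04 (adjusted p = 0.227 and 0.564). CD86 no longer passed with no filter (adjusted p = 0.0606) or with a variance that does not follow signal (adjusted p = 0.16). The 3 that fell were CD70, TNFRSF9 and TNFSF4, members of the TNF and TNF receptor families, with CD70 going from 325 to 191, and IL23A fell from 199 to 67.8 (-1.21 ± 0.16). The chemokine CCL17 rose from 9690 to 13920, and CXCL16 fell from 3582 to 2156.

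Among 33 type I interferon-stimulated genes 8 rose and none fell in matched against unloaded cells (median 0.29, 11 adjusted over the list alone, list adjusted p = 8.49e-08). ISG20 went from 497 to 852, ISG15 from 115 to 236 and HERC5 from 106 to 234. Of 16 heat shock and chaperone genes 9 rose (median 0.28, 10 adjusted over the list alone, list adjusted p = 9.45e-07), HSPB1 from 559 to 1085 among them. Of 24 proteasome subunits 8 rose (median 0.20, 10 adjusted over the list alone, list adjusted p = 1.37e-07). These 3 lists had adjusted p = 0.629 with an estimated correlation. The unfolded protein response list fell, with 8 of 22 members lower and 1 higher (median -0.22, 10 adjusted over the list alone, list adjusted p = 0.00111; adjusted p = 0.652 with an estimated correlation), and its median was -0.093 after quantile normalization and -0.065 after centring. Set against the median of all genes, that of this list was -0.143 as deposited. Its members that moved most included ASNS, ATF4 (3510 to 2028) and CHAC1 (106 to 19.3), which also belong to the response to amino acid shortage, beside XBP1 (508 to 227), HERPUD1 and DNAJB9 of the endoplasmic reticulum response.

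Of 16 genes of endocytic uptake and scavenger receptors 5 fell and 1 rose in matched against unloaded cells (median -0.18, 6 adjusted over the list alone, list adjusted p = 0.0329; adjusted p = 0.652 with an estimated correlation). The Fc receptor FCGR2A went from 355 to 111 and the oxidised lipoprotein receptor OLR1 from 267 to 90.6. Of 19 genes of MHC class II presentation 6 fell (median -0.18, 7 adjusted over the list alone, list adjusted p = 0.0474), the class II transactivator CIITA from 294 to 118 and HLA-DMB from 698 to 483. After quantile normalization and after centring the endocytic list had medians of -0.073 and -0.026, and the MHC class II list of -0.089 and -0.031. Set against the median of all genes, these lists had -0.103 and -0.109 as deposited. The lists that were higher had larger medians under both, except that oxidative phosphorylation was 0.144 after quantile normalization against 0.151 as deposited. The upward shift of centring alone would give larger medians. After centring the medians were 0.237 for MHC class I, 0.192 for NF-kappaB targets, 0.445 for interferon-stimulated genes, 0.348 for the proteasome, 0.435 for heat shock, 0.302 for oxidative phosphorylation and 0.261 for cholesterol biosynthesis (0.11 as deposited). After quantile normalization NF-kappaB targets had 0.096, MHC class I 0.124 and cholesterol biosynthesis 0.24. Of 20 genes of MHC class I presentation 3 rose (median 0.09, 8 adjusted over the list alone, list adjusted p = 0.0108). Of 20 NF-kappaB target genes 3 rose, TRAF1, BCL2A1 and NFKBIA (median 0.04, 4 adjusted over the list alone, list adjusted p = 0.0433). The MHC class II, MHC class I and NF-kappaB lists had adjusted p = 0.774 with an estimated correlation. Of 15 cholesterol biosynthesis genes MSMO1, SC5D and STARD4 rose (list adjusted p = 0.0108; adjusted p = 0.652 with an estimated correlation; 4 adjusted over the list alone). Of 23 oxidative phosphorylation genes CYC1 and ATP5F1A rose (list adjusted p = 0.000378; adjusted p = 0.687 with an estimated correlation; 1 adjusted over the list alone).

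For matched against unloaded cells, 3303 probe sets passed, 719 higher and 2584 lower, in 1576 genes (455 higher, 1121 lower), of which 12 rose and 98 fell by more than 2-fold; the lower share was 78.2% as deposited, 52.1% after quantile normalization and 39.7% after centring. The 3' to 5' signal ratio of ACTB, a sign of RNA quality, was 2.46 and 2.18 on the unloaded arrays and 2.1 and 1.95 on the matched arrays. With that ratio as a covariate, added after it was seen, 771 probe sets passed (172 higher, 599 lower), and CD40 (adjusted p = 0.15), CD86 (adjusted p = 0.209) and IL12B (adjusted p = 0.0767) no longer passed. With it CD86 differed by 0.266 ± 0.104 and IL12B by 0.498 ± 0.144, about as much as before with wider errors, and CD40 by 0.39 ± 0.135 against 0.52 ± 0.09. Without unloaded replicate 1 the count was 1710, without matched replicate 1 or 2 it was 1806 or 1819, and with a variance that does not follow signal it was 1745.

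Matched cells were compared with cells given mRNA alone. CD52 rose from 1162 to 3549 (1.58 ± 0.08, adjusted p = 1.1e-09), MUCL1 from 138 to 416, lipoprotein lipase, LPL, from 173 to 499 (1.38 ± 0.11), the drug transporter ABCG2 from 97.2 to 274 and HSD11B1, an enzyme that forms cortisol from cortisone, from 254 to 584. PSAT1 fell from 1325 to 68.2 (-3.76 ± 0.11), ASNS from 541 to 55.4 (-2.71 ± 0.11), DDIT4 from 664 to 179, and the amino acid transporter SLC7A5 from 181 to 43.1 (-1.51 ± 0.15). Of 23 lysosome genes 9 rose and 1 fell (median 0.26, 13 adjusted over the list alone, list adjusted p = 8.37e-09). GLA, CTSL, LIPA and CTSD were among those that rose, LIPA from 8792 to 11510. Of 18 genes of monocyte-derived DC identity 3 rose, MRC1 (1511 to 2330), CD1B (89.8 to 206) and CCL17 (median 0.22, 6 adjusted over the list alone, list adjusted p = 0.0155). Of 16 heat shock genes 5 rose (median 0.20, 7 adjusted over the list alone, list adjusted p = 0.000159). Of 24 proteasome subunits 2 rose (median 0.09, 4 adjusted over the list alone, list adjusted p = 0.000159) and of 23 oxidative phosphorylation genes 1 rose (median 0.14, 1 adjusted over the list alone, list adjusted p = 0.000105). Those 5 lists had adjusted p = 0.742 with an estimated correlation. Of 22 unfolded protein response genes 7 fell (median -0.16, 10 adjusted over the list alone, list adjusted p = 0.00694; adjusted p = 0.761 with an estimated correlation), with a median of -0.074 after quantile normalization and -0.04 after centring. Set against the median of all genes, the unfolded protein response list had -0.098 as deposited. The medians of the higher lists were larger after centring, as its upward shift of every probe set requires. They were 0.337 for DC identity, 0.318 for heat shock, 0.205 for the proteasome (0.166 after quantile normalization) and 0.255 for oxidative phosphorylation. In all 2185 probe sets passed, 425 higher and 1760 lower. The lower share was 80.5% as deposited, 55% after quantile normalization and 45.6% after centring. Without mRNA replicate 1 or 2 the count was 1101 or 894, without matched replicate 1 or 2 it was 1181 or 958, and with a variance that does not follow signal it was 909.

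Against cells given lysate alone, matched cells held higher MLLT11 (379 to 836, 1.08 ± 0.11, adjusted p = 8.7e-05), CSRP2 (195 to 444), MOCOS (124 to 289), PRAME (188 to 390) and the oxidative stress enzyme NQO1 (485 to 938). PSAT1 fell from 544 to 68.2 (-2.53 ± 0.11), ASNS from 291 to 55.4 (-1.89 ± 0.11), CCL26 from 331 to 78.4, the C-type lectin CD209 from 318 to 135 and the integrin ITGAM from 877 to 421. Of 16 genes of endocytic uptake 5 fell (median -0.26, 7 adjusted over the list alone, list adjusted p = 9.81e-05), FCGR2A, CLEC4A, MRC1, FCGR2B and LRP1. Of 18 genes of monocyte-derived DC identity 5 fell and 1 rose (median -0.03, 8 adjusted over the list alone, list adjusted p = 0.0404). Of 23 maturation and costimulation genes CD80 and CD58 rose and TNFRSF9 fell (median 0.13, 4 adjusted over the list alone, list adjusted p = 0.0402). Of 24 proteasome subunits PSMA2, PSMB2 and PSMA5 rose (median 0.22, 13 adjusted over the list alone, list adjusted p = 1.22e-08). Of 33 interferon-stimulated genes EPSTI1 and ISG20 rose (median 0.25, 7 adjusted over the list alone, list adjusted p = 0.000656). The heat shock, MHC class I, NF-kappaB, oxidative phosphorylation and ribosomal protein lists passed too, all on the higher side, with 2, 1, 1, 0 and 0 members past the threshold and 6, 4, 2, 6 and 0 adjusted over the list alone (list adjusted p = 0.00249, 0.00106, 0.0442, 2.3e-05 and 0.00181). At an unadjusted p under 0.05 in limma, 10 oxidative phosphorylation genes and 9 ribosomal protein genes differed. All 10 lists had adjusted p = 0.74 with an estimated correlation, and the ribosomal protein list turned its sign after quantile normalization (-0.005 against 0.097). The maturation, MHC class I and NF-kappaB lists had medians of 0.044, 0.055 and 0.072 after quantile normalization against 0.129, 0.134 and 0.151 as deposited, and the DC identity list of 0 after centring. In all 639 probe sets passed, 283 higher and 356 lower. Counted by gene the direction turned, with 335 genes (182 higher, 153 lower). Of the calls, the lower share was 55.7% as deposited, 62.5% after quantile normalization and 39.1% after centring. The direction rested on single lysate arrays, with 339 higher and 88 lower without lysate replicate 1 and 99 higher and 332 lower without lysate replicate 2. The ACTB ratio was 2.1 and 1.95 on the matched arrays and 1.78 and 1.75 on the lysate arrays, and with it as a covariate 102 probe sets passed (43 higher, 59 lower). Without matched replicate 1 or 2 the count was 213 or 121, and with a variance that does not follow signal it was 13.

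The design text asks for genes in matched cells that differ from all 4 other groups. MLLT11 stood at 836 in matched cells against 379 to 476 elsewhere (smallest of the 4 differences 0.78), PRAME at 390 against 185 to 241, CLU at 784 against 298 to 499, and EBI3 at 1442 against 862 to 976. MOCOS, ARHGAP22, DCTPP1, HSPB1, CBR3, CPEB1 and ENO3 were also higher. USP9X was at 1052 against 675 to 717, with an SD of 296 between the matched arrays, and another of its probe sets fell against mismatched (-0.628), unloaded (-0.661) and mRNA cells (-0.496). On the lower side, PSAT1 had means of 2135 in unloaded, 1325 in mRNA, 544 in lysate, 282 in mismatched and 68.2 in matched cells (SD 109, 109, 63.9, 1.13 and 12.5). ASNS followed the same order, with means of 897, 541, 291, 139 and 55.4. FCGR2A was at 111 against 234 to 355, CCL26 at 78.4 against 170 to 376, and ANP32E, a chromatin-associated protein, at 711 against 1199 to 1589. SLC7A5, CD14, DDIT4, ZNF652, STK40, LFNG and DCAF4 were also lower, DCAF4 at signals under 40 in every group.

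**Figure D3:**
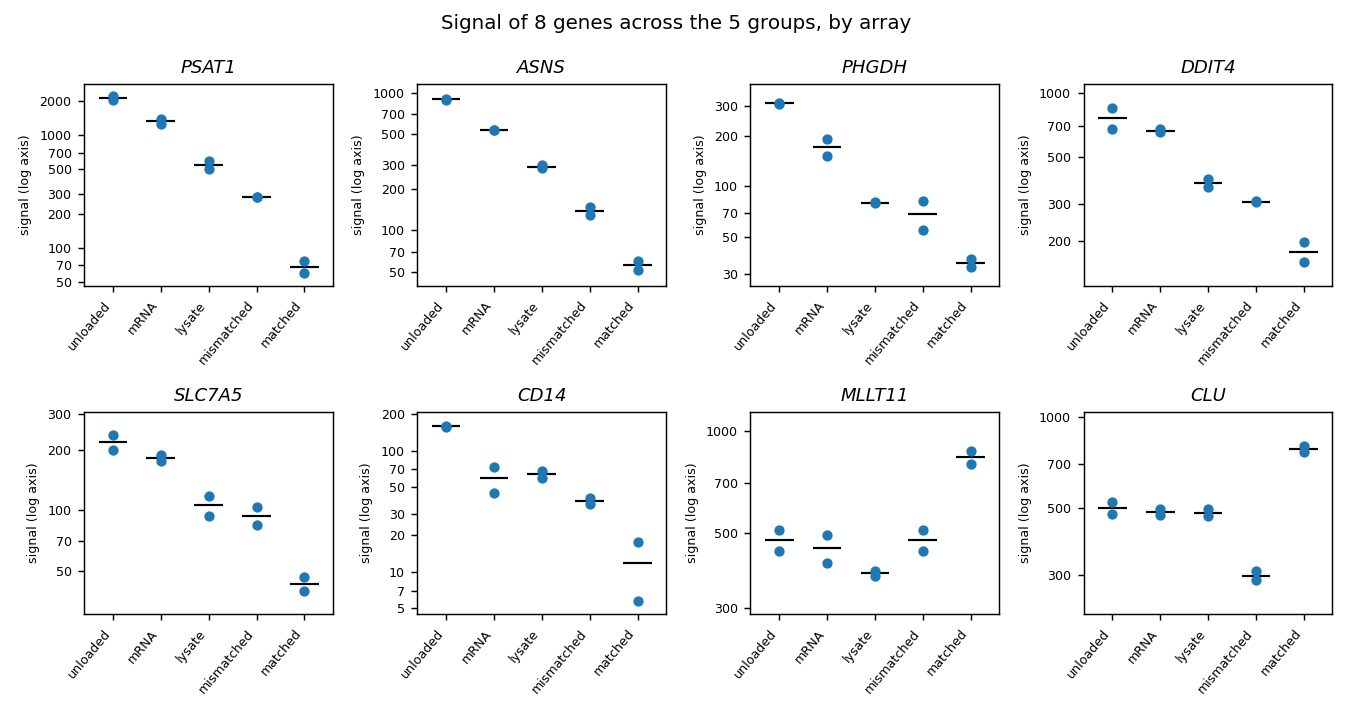
Signal of 8 genes on each array, on log axes that do not start at 0. Each point is 1 array, horizontal lines are means of the 2 arrays of a group, and groups run from unloaded to matched cells; PSAT1 went from 2135 in unloaded to 68.2 in matched cells, while MLLT11 and CLU were highest in matched cells at 836 and 784.

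In this test 232 probe sets passed in all 4 comparisons, 41 higher and 191 lower, in 88 genes (29 higher, 59 lower). Independent lists of the same sizes would share 0.00156 higher and 0.0778 lower, and 20 simulations with no effect, in which the 4 comparisons used the same matched arrays, gave 0 at the adjusted threshold; at an unadjusted p under 0.05 in all 4, 1240 were observed against a simulated mean of 48.5. All 4 comparisons rest on the same 2 matched arrays, which the figure for independent lists ignores. The simulated values had the moderated variances of the fit, varied independently between probe sets and held no difference between donors or arrays. A count of 0 at the adjusted threshold was therefore near certain beforehand. These counts cannot tell an effect of matched loading from a trait of these 2 arrays or their donors. Of the calls, the lower share was 82.3% as deposited, 74.9% after quantile normalization and 40.1% after centring, and with the threshold of the design text 51 passed (7 higher, 44 lower). Without matched replicate 1 or 2 the count was 103 or 55, without mismatched replicate 1 or 2 it was 95 or 116, without lysate replicate 1 it was 110 (59 higher, 51 lower), and with a variance that does not follow signal it was 9. With no filter 81 passed (11 higher, 70 lower), and with the ACTB ratio as a covariate 33 (5 higher, 28 lower).

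Cells given mRNA alone were compared with unloaded cells. CLC rose from 72.1 to 187 (1.08 ± 0.13), the aldo-keto reductases AKR1C2 and AKR1C1 from 83.3 to 209 and from 145 to 305, and the tubulin gene TUBB2B from 761 to 1453 (0.91 ± 0.09, adjusted p = 6.6e-05). The chemokine XCL1 fell from 190 to 59.1, CHI3L1 from 137 to 40 and carbonic anhydrase CA2 from 373 to 164. Of 33 type I interferon-stimulated genes 5 rose and none fell (median 0.30, 10 adjusted over the list alone, list adjusted p = 4.97e-10; adjusted p = 0.296 with an estimated correlation), ISG20, SAMD9L, ISG15, HERC5 and MX1. Of 16 genes of endocytic uptake 6 fell (median -0.31, 11 adjusted over the list alone, list adjusted p = 7.98e-05; adjusted p = 0.332 with an estimated correlation), with MRC1 going from 2441 to 1511 and OLR1 from 267 to 115. Of 18 genes of monocyte-derived DC identity 5 fell and 1 rose (median -0.27, 9 adjusted over the list alone, list adjusted p = 0.000778). Of 23 lysosome genes 2 fell, CTSL and ASAH1 (median -0.19, 10 adjusted over the list alone, list adjusted p = 4.89e-06). Both lists had adjusted p = 0.657 with an estimated correlation. Of 11 monocyte and macrophage markers CD14 and C1QB fell (median -0.29, 3 adjusted over the list alone, list adjusted p = 0.00112; adjusted p = 0.296 with an estimated correlation). The lists for MHC class II presentation (2 members lower, 4 adjusted over the list alone, list adjusted p = 0.044), interferon-gamma-induced genes (2 higher, 4 over the list alone, 0.0158), NF-kappaB targets (1 higher, 4 over the list alone, 0.000949), cholesterol biosynthesis (2 higher, 2 over the list alone, 0.026), cholesterol efflux (2 higher, 2 over the list alone, 0.0331) and heat shock genes (0 members, 1 over the list alone, 0.0158) passed too, with adjusted p = 0.765 with an estimated correlation. The proteasome list also passed (0 members, 0 adjusted over the list alone, list adjusted p = 0.0192; adjusted p = 0.814 with an estimated correlation), and 5 heat shock and 4 proteasome genes had an unadjusted p under 0.05 in limma. The cholesterol efflux list had a median of 0.048, and of 0.081 after centring. IL12B rose from 787 to 1223 (0.62 ± 0.09). In all 437 probe sets passed, 181 higher and 256 lower. Lower calls made up 58.6% as deposited, 51.8% after quantile normalization and 42.5% after centring. The ACTB ratio was 1.99 and 1.83 on the mRNA arrays. With it as a covariate 13 probe sets passed, and with a variance that does not follow signal 1 passed. Without mRNA replicate 1 or 2 the count was 196 or 198, and without unloaded replicate 1 or 2 it was 220 (111 higher, 109 lower) or 268.

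Cells given lysate alone were compared with unloaded cells. CLC rose from 72.1 to 254 (1.47 ± 0.13, adjusted p = 9.64e-06), CRABP2 from 72.9 to 238, TIMP3 from 121 to 265, the Notch ligand JAG1 from 146 to 306 and CD52 from 1687 to 3095 (0.86 ± 0.08). GREM1, an antagonist of bone morphogenetic proteins, fell from 2736 to 851 (-1.65 ± 0.09, adjusted p = 1.44e-08), PSAT1 from 2135 to 544 (-1.91 ± 0.11), ASNS from 897 to 291 (-1.52 ± 0.11), PHGDH from 312 to 80.1 and IFRD1 from 2001 to 815. Of 22 unfolded protein response genes 6 fell (median -0.19, 10 adjusted over the list alone, list adjusted p = 0.00163). Of 19 MHC class II genes 6 fell and CTSL rose (median -0.24, 13 adjusted over the list alone, list adjusted p = 0.0417). Of 15 cholesterol biosynthesis genes MSMO1, ACAT2 and INSIG1 rose (median 0.12, 4 adjusted over the list alone, list adjusted p = 0.000389). Of 15 interferon-gamma-induced genes GBP1 and SOCS1 rose and CIITA fell (median 0.11, 6 adjusted over the list alone, list adjusted p = 0.00163). Those 4 lists had adjusted p = 0.602 with an estimated correlation. Of 25 autophagy genes 4 fell, GABARAPL1 from 383 to 168 among them (median -0.14, 8 adjusted over the list alone, list adjusted p = 0.0479; adjusted p = 0.806 with an estimated correlation). Of 19 p53 response and apoptosis genes 5 fell, SESN2 from 488 to 235 and BCL2L11 from 2736 to 1868 among them (median -0.18, 7 adjusted over the list alone, list adjusted p = 0.0417; adjusted p = 0.726 with an estimated correlation). The lists for monocyte-derived DC identity (1 member higher, 1 adjusted over the list alone, list adjusted p = 0.0479), interferon-stimulated genes (1 higher, 2 over the list alone, 0.000717), chemokines (1 higher and 1 lower, 3 over the list alone, 0.0479), lysosome genes (1 higher and 1 lower, 3 over the list alone, 0.00163), heat shock genes (2 higher, 4 over the list alone, 0.000581) and cholesterol efflux (2 higher and 2 lower, 5 over the list alone, 0.0192) passed too, with adjusted p = 0.602 with an estimated correlation. After quantile normalization and after centring the medians were -0.085 and -0.062 for the unfolded protein response, -0.138 and -0.119 for MHC class II, -0.038 and -0.014 for autophagy and -0.05 and -0.058 for the p53 list. The higher lists had larger medians under both, which the upward shift of centring alone would give. The medians were 0.216 and 0.232 for interferon-gamma-induced genes, 0.251 and 0.247 for cholesterol biosynthesis, 0.188 and 0.191 for DC identity (0.067 as deposited) and 0.157 and 0.201 for interferon-stimulated genes (0.077). They were 0.202 and 0.206 for chemokines (0.081), 0.178 and 0.187 for lysosome genes (0.063), 0.194 and 0.229 for heat shock genes (0.104) and 0.183 and 0.197 for cholesterol efflux (0.073). In all 1267 probe sets passed, 193 higher and 1074 lower. Lower calls made up 84.8% as deposited, 48.2% after quantile normalization and 46.8% after centring. The ACTB ratio was 1.78 and 1.75 on the lysate arrays. With it as a covariate 8 probe sets passed, and CIITA differed by 0.01 ± 0.30, against -0.58 ± 0.15 without it. Without unloaded replicate 1 the count was 396, without lysate replicate 2 it was 433, and with a variance that does not follow signal it was 182.

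Mismatched cells were compared with unloaded cells. CLC rose from 72.1 to 264 (1.52 ± 0.13), AKR1C1 from 145 to 391 (1.26 ± 0.12, adjusted p = 1.08e-05), ARHGAP22 from 49.3 to 161 and the chaperone regulator BAG2 from 94.8 to 221. PSAT1 fell from 2135 to 282 (-2.79 ± 0.11, adjusted p = 1.13e-10), ASNS from 897 to 139 (-2.45 ± 0.11), PCK2 from 992 to 261 and carbonic anhydrase CA2 from 373 to 109. IL12B rose from 787 to 1541 (0.94 ± 0.09, adjusted p = 1.16e-05), CXCL8 from 1197 to 2080 and CCL19 from 265 to 466. CD80 (1517 to 2018) and CD40 (875 to 1137) rose, and CD274, the ligand PD-L1, fell from 6470 to 5225. Of 22 unfolded protein response genes 10 fell, HSPA5 from 2637 to 1636 among them (median -0.34, 11 adjusted over the list alone, list adjusted p = 8.08e-06). Of 19 MHC class II genes 7 fell (median -0.24, 10 adjusted over the list alone, list adjusted p = 2.14e-05). Of 15 cholesterol biosynthesis genes 5 rose, MSMO1 from 521 to 1015 among them (median 0.24, 5 adjusted over the list alone, list adjusted p = 2.77e-05). These 3 lists had adjusted p = 0.638 with an estimated correlation. Of 16 genes of endocytic uptake 7 fell and 1 rose (median -0.35, 9 adjusted over the list alone, list adjusted p = 0.0114). Of 33 interferon-stimulated genes 3 rose (median 0.09, 6 adjusted over the list alone, list adjusted p = 0.00154). Of 20 NF-kappaB target genes 4 rose (median 0.10, 4 adjusted over the list alone, list adjusted p = 0.000424). These 3 lists had adjusted p = 0.729 with an estimated correlation. Of 15 interferon-gamma-induced genes 3 rose and 2 fell (median 0.14, 7 adjusted over the list alone, list adjusted p = 0.0106). Of 16 heat shock genes 3 rose (median 0.09, 4 adjusted over the list alone, list adjusted p = 0.0106). Both lists had adjusted p = 0.739 with an estimated correlation. Of 27 ribosomal protein genes 3 fell (median -0.14, 9 adjusted over the list alone, list adjusted p = 0.000596; adjusted p = 0.778 with an estimated correlation), with a median of -0.045 after quantile normalization and -0.085 after centring. After quantile normalization and after centring the medians were -0.152 and -0.189 for MHC class II, 0.19 and 0.15 for NF-kappaB targets, 0.154 and 0.138 for heat shock genes, 0.218 and 0.189 for interferon-gamma-induced genes and 0.136 and 0.146 for interferon-stimulated genes. In all 1644 probe sets passed, 447 higher and 1197 lower. Lower calls made up 72.8% as deposited, 52.0% after quantile normalization and 56.8% after centring. The ACTB ratio was 1.92 and 1.76 on the mismatched arrays. With it as a covariate 48 probe sets passed. Without mismatched replicate 1 or 2 the count was 688 or 699, without unloaded replicate 1 or 2 it was 896 or 1062, and with a variance that does not follow signal it was 416.

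Lists of markers of other cell types that a blood-derived culture can hold gave few calls. The lists for T cells, B and plasma cells, NK cells, neutrophils, erythroid cells, epithelial cells, melanocytes and plasmacytoid DCs held 3 to 6 measured genes each, with no member past the threshold in any of the 7 comparisons and 15 of 224 gene-by-comparison results at an unadjusted p under 0.05 in limma, and none of these 8 lists passed (lowest list adjusted p = 0.171, T cell markers in matched against lysate cells). T cell markers held most of these 15 results, a larger share of their own tests than the 0.05 that unchanged genes would give. Of 5 measured T cell genes, 2 each were in matched against mismatched (list median 0.118) and against lysate cells (list median 0.335). T cell markers had 0 in mismatched against unloaded cells and 1 in each of the other comparisons. Of 7 platelet markers GP1BA rose from 242 to 363 and MYL9 from 41.5 to 84 in matched against unloaded cells, where the list had adjusted p = 0.0614 (0.629 with an estimated correlation) and passed with fry, which does not compare it with other genes (adjusted p = 0.0264). Both genes also rose in matched against mRNA cells, GP1BA in matched against lysate cells and MYL9 in lysate against unloaded cells, and the list did not pass in any of the 7 comparisons (lowest list adjusted p = 0.0515, in lysate against unloaded cells). Of 7 haematopoietic progenitor markers MYB rose from 52.6 to 112 in matched against unloaded cells, where the list did not pass (1 adjusted over the list alone, list adjusted p = 0.354). The list passed in lysate against unloaded cells, with no member past the threshold and 1 at an unadjusted p under 0.05 in limma (median 0.26, 1 adjusted over the list alone, list adjusted p = 0.0323; adjusted p = 0.602 with an estimated correlation). CLC, an eosinophil and basophil gene that no fixed list held, rose from 72.1 in unloaded cells to 187 in mRNA, 254 in lysate, 264 in mismatched and 355 in matched cells. Of a list of other eosinophil and basophil markers chosen after CLC was seen, 7 were measured, 3 of which (GATA1, GATA2 and CPA3) are also progenitor markers. None of the 7 passed in any of the 7 comparisons and 2 results had an unadjusted p under 0.05 in limma (EPX -0.632 in lysate against unloaded cells, ENPP3 0.64 in matched against mismatched cells). Their signals lay between 15 and 43.1 in unloaded cells, and the list had a median of 0.149 in matched against unloaded cells (unadjusted p = 0.302 in limma's camera). Because the design text gives every population its own donor, group and donor are not separated in these comparisons.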

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

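The tests of array scaling on both patterns below, of different donors, of shared donors within a group and of donor makeup between groups were chosen after the result was seen. The others were set before their own result was seen. The list of amino acid response genes was itself chosen after the values were seen, so every test on it was set with that pattern known. The test of RNA quality is among the others, but the ACTB ratio it uses was added as a covariate after the arrays had been seen. The interaction test, limma with 2 arrays per group, asked whether adding mRNA acted differently in cells given matched lysate than in cells given no lysate, and 151 probe sets passed (72 higher, 79 lower). Without unloaded replicate 1 the count was 94, without mRNA replicate 1 or 2 it was 63 or 71, and without matched replicate 1 or 2 it was 96 or 65. The direction of the calls rested on single arrays, with 93 higher and 32 lower without lysate replicate 1, 47 and 133 without lysate replicate 2, and 46 and 25 without mRNA replicate 2. With the ACTB ratio as a covariate 2 probe sets passed, with a variance that does not follow signal 3, and with no filter 49.

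GREM1 had the largest positive interaction, 1.696 ± 0.121 (adjusted p = 2.46e-06): mRNA alone went with a fall from 2736 to 1362, while mRNA on top of lysate went from 851 to 1404. BEX1 (1.337), IGFBP7 (1.299), CD1B (1.185), ITPR1 (1.171) and CHI3L1 (1.169) were also lower with mRNA alone. PRAME (1.207) had 241.4 and 194.5 without lysate and 188.4 and 389.9 with it, and MLLT11 (1.155) had 476 and 450 without lysate and 379 and 836 with it. HIPK4 (1.527) and ITGB5 (1.469) had signals under 63 in every group. In mismatched cells, which this test leaves out, GREM1 was at 1113, also above its signal with lysate alone. PRAME and MLLT11 were at 184.9 and 476 there, below their matched signals. A departure like that of GREM1 may thus not be particular to matched antigens, and an interaction with mismatched loads was not tested.

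PSAT1 (-1.848) and ASNS (-1.189) had negative interactions, since PSAT1 differed by -0.68 with mRNA alone and by -2.53 with mRNA on lysate. CBLB (-0.978), CNN3 (-0.957), IRS2 (-0.954), INSIG1 (-0.949), ANKRD37 (-1.094), BMS1P1 (-1.091) and LFNG (-1.125) were higher with mRNA alone and lower with mRNA on lysate. TUBB2B (-0.978) was higher with mRNA alone, at 761 and 1453, and had 798 and 759 on lysate, a difference of -0.072. Its signal in mismatched cells was 875.5, also far below that with mRNA alone.

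Lower calls outnumbered higher calls in matched against unloaded cells, 2584 to 719. After centring each array on its median 39.7% of the calls were lower, against 78.2% as deposited, but centring balances the calls whatever the cause. Array scaling and a true excess of lower genes therefore cannot be told apart. A background difference in dim probe sets is argued against as the whole cause by the brightest of 3 equal bins by signal, where 73.2% of the calls were lower, but the share was 83.2% in the dimmest and 90% in the middle bin, so a part in it stays open. No biological explanation of the excess was tested.

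Genes of the amino acid response driven by the transcription factor ATF4, a list of 46 measured genes chosen after the values were seen, had median differences from unloaded cells of -0.275 in mRNA, -0.608 in lysate, -0.774 in mismatched and -0.97 in matched cells. The 32 members that the naming rule did not pick still had -0.281, -0.518, -0.663 and -0.727; between matched and mismatched cells they differed by -0.023 (2 lower) and the full list by -0.135 (10 lower; -0.09 after quantile normalization and -0.036 after centring), but the rule picks by that same change, so this split decides nothing about that step. Array scaling and RNA quality, as read by the ACTB ratio, are argued against as the whole cause of the matched fall. The matched median was -0.819 after centring and -1.017 with that ratio as a covariate (median standard error 0.17), with 41 of 46 genes lower. The median standard error is that of the single genes' errors, not an error of the list's median. The slope on the ratio comes only from differences between the 2 arrays of a group. With it the medians were -0.251 in mRNA, -0.575 in lysate and -0.751 in mismatched cells (median standard errors 0.209, 0.262 and 0.234). In mRNA cells 33 of 46 genes were lower with it. The mRNA median lay within 2 such single-gene errors of 0, which is no test of the list, so RNA quality stays open there. The 6 measured transfer RNA synthetases outside the list had a median of 0.171 in matched against unloaded cells. That is beyond the bound of 0.15 set for lower amino acid starvation signalling, and not lower as a loss in all synthetases would need. Over the 17 cytosolic synthetases measured the median was -0.665, with 10 lower and 1 higher. With 6 genes left outside a list chosen after the values were seen, this test cannot decide, so lower starvation signalling stays open. Different donors cannot be told apart from loading, because the design holds no donor in more than 1 group; the gap between the 2 arrays of a group, 0.084, does not bear on this.

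Both arrays of a group lay close together although the design text names a separate donor for each population. Genes whose level can follow genotype, 25 probe sets, had as a set a within-group SD 0.968 times that of random probe sets of like signal and a between-group SD 1.44 times theirs. Without the HLA genes among them the ratios were 1.09 and 1.4. Shared donors within a group, as in a pool or a repeated array, may account for the first ratio and different donors between groups for the second, while an effect of loading on these genes was not separated from donors. In that case the p-values of every comparison would measure the spread between arrays and not between donors.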

How the results depend on the processing

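The fit with the ACTB ratio as a covariate and the fit without the unloaded arrays were chosen after the arrays had been seen, and the other alternatives were planned. Counts of probe sets past the threshold are given for matched against mismatched, unloaded, mRNA and lysate cells, then for mRNA, lysate and mismatched against unloaded cells, unless named. A smaller and a larger pseudocount, robust variances and the fit without unloaded arrays kept every count they gave within 1.5 times. So did a replicate block (1291, 3303, 2196, 657, 424, 1232 and 1602), although the numbers are not known to pair the arrays, and same-numbered deviations correlated at -0.018 to 0.045 over 10 pairs of groups. Of 639 calls of named genes, 606 held after quantile normalization, 597 after centring, 421 with no filter, 238 with a variance that does not follow signal and 218 with the ACTB ratio. With no detection calls used here, signal over background limits what dim genes can show. The cause was not tested for any of the changes below, except that no filter raises the number of tests.

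After quantile normalization the count was 1049 in matched against lysate cells (5 lists), 839 in mRNA against unloaded, 436 in the interaction and 351 against all 4 groups, and the ribosomal protein list in matched against lysate cells turned to -0.005. After centring it was 2263 in matched against mismatched, 1271 in matched against lysate, 746 in mRNA against unloaded, 317 in the interaction and 476 against all 4. With no filter the counts were 569, 2125, 1295, 202, 244, 645 and 1072, with 49 in the interaction, 81 against all 4 and 2079 for any difference. With a stricter filter they were 1089 in matched against lysate, 302 in the interaction and 399 against all 4. With a variance that does not follow signal they were 169, 1745, 909, 13, 1, 182 and 416, with 3 in the interaction, 9 against all 4 and 857 for any difference. With only the groups compared, lysate against unloaded gave 782. With the threshold of the design text the counts were 468, 1602, 985, 151, 204, 442 and 784, and 51 against all 4. With 1 probe set per gene they were 585, 1647, 1078 and 419 for the matched comparisons, 820 and 1035 for lysate and mismatched against unloaded, 87 in the interaction, 107 against all 4 and 2116 for any difference. With the ACTB ratio they were 745, 771, 102 (matched against lysate), 13, 8 and 48 (against unloaded), 2 in the interaction and 33 against all 4, with 6 lists in matched and 4 in lysate against unloaded cells; in lysate against unloaded cells CIITA turned to 0.011 and IL1RN to -0.099.

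With an estimated correlation 0 lists passed in each of the 7 comparisons, with 0, 1, 2, 1, 3, 1 and 2 lists at an unadjusted p under 0.05 in limma's camera. With fry 0 lists passed in matched against mismatched, mRNA and lysate cells and in lysate against unloaded cells, with 6, 6, 7 and 8 at an unadjusted p under 0.05, and 3 passed in mRNA, 3 in mismatched and 7 (4 higher, 3 lower) in matched against unloaded cells.

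Leaving out each array in turn leaves 1 array in a group, assumed to vary like the others. The counts ran from 292 to 1580, 1710 to 3587, 894 to 2535, 121 to 702, 196 to 554, 396 to 1619 and 688 to 1927, from 63 to 180 in the interaction, 55 to 235 against all 4 and 2425 (without matched replicate 2) to 4344 for any difference. The lists ran from 6 to 7, 5 to 13, 6 to 8, 7 to 10, 5 to 13, 7 to 14 and 6 to 10. Matched against unloaded cells had 5 lists without matched replicate 2, mRNA against unloaded had 5 without unloaded replicate 2, and lysate against unloaded had 8 or 7 without unloaded replicate 1 or 2.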
